A study of Macaca mulatta with 9 samples.

How the data were processed

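The series measured total RNA from formalin-fixed, paraffin-embedded renal biopsies of pig kidney xenografts in rhesus macaques on the nCounter Human Organ Transplant Panel. The labels require a minimum 260:280 absorbance ratio of the RNA and describe no step after counting. The 9 samples were placed in 3 groups of 3 from their titles. The labels do not say whether equal replicate numbers mark the same animal, or whether the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may in part be technical. The probes were designed against human transcripts. How each binds pig or macaque RNA, or a human transgene as against the host's own gene, is not given in the sources used here, so a value is the signal of the probe and not of a named species' transcript. Probes that the table marks as macaque or pig were taken to read that species, which was not checked.

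The deposited values are log2 values, and 2 to the power of each one was a whole number for 100% of the 767 probes in all 9 libraries, within a relative tolerance of 1e-04, the smallest being 1. They are therefore log2 of whole counts. Because their totals differed widely between libraries, no scaling between samples by the authors is visible in them. Whether 1 was added before the log is not given in the sources used here; taking 1 from every count was tried as an alternative. The whole numbers were used as counts, so all totals and counts in the text rest on this reading. No probe was left out, and every column of the table was used.

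The planned fit had provided for log2 values to be used as they stood and for raw counts to be tested with a quasi-likelihood count model and trimmed-mean scaling. The values turned out to be both, log2 of unscaled counts, so the fit settled on is neither as written. The count model itself was not run, by choice, although whole counts were recovered. The fit used is a form of the count plan in limma: voom on the recovered counts with an offset of 0.5, library sizes multiplied by trimmed-mean factors (trims of 0.3 and 0.05), and lmFit with eBayes over all 9 libraries in 3 group means. This was chosen after the unit was known and after several fits had been viewed side by side; the fit of the values as deposited, unscaled, is given among the alternatives. R 4.3.3 and limma 3.58.1 were used. The factors ranged from 0.761 to 2.71, the last being that of the library with 21725 counts. Tests were two-sided, adjusted by Benjamini-Hochberg over 767 probes, and called at 0.05. Fold changes were taken from the fitted log2 CPM, counts scaled to library size. Between libraries of like size, background makes them understate changes of low probes. In the library with 21725 counts the viral probes gave a mean of 5.25 counts, against 5 to 10.25 in the others. Over its effective size of 58880 such background gives high scaled values, so low probes can be raised in it. SE is the moderated standard error.

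Before the data were examined, 24 gene lists, the alternatives and the rule for named genes were fixed. The lists came from general knowledge of transplantation. The transgene list was written as the genes believed, from field knowledge, to be carried by the 3KO.7TG line. The labels name none of them, and 5 of its members were measured. Lists with at least 5 measured members, 21 in all, were tested with fry, which asks whether members move one way on balance, with adjustment over the 21 lists; the proliferation, vessel blood cell and viral lists had fewer. 17 genes are in more than 1 list, CD46 and CD55 being in the complement list and THBD in the endothelial and coagulation lists. Named genes per comparison were the 8 largest rises and the 8 largest falls among called genes with no overlap between groups, or all if fewer passed, or the 5 smallest unadjusted p where none passed; all measured transgene-list genes; and the 2 members with the largest moderated t of each described list, up to 4 of a called one. Genes named outside this rule are marked in the text, and not every gene that the rule picks is printed.

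Scalings tried were median, housekeeping list, quantile and, added after the data were seen, none, pig reference probes and macaque reference probes. Other alternatives changed the pseudocount, a filter on means under 20, the eBayes prior, the samples in the fit, a replicate block, the set test and each left-out library. Added after the data were seen were fits without voom weights, with a weight per library, with the viral probe mean subtracted, and without the low-yield library together with another choice. Simulated counts for 1KO.1TG early R against 3KO.7TG early bx, with 200 of 767 probes changed, were drawn from the real means and effective (trimmed-mean scaled) library sizes. They were used to test the fit. With all 9 libraries it recovered 16% of probes changed by 1 on the log2 scale, 68% of those changed by 2, 82% by 3 and 88% by 7, and called 0.529% of unchanged probes. Without the low-yield library these were 30%, 76%, 92%, 98% and 0.529%. The low-yield library was simulated at an effective size of 58880, above its 21725 counts, and otherwise like the other libraries. All probes shared 1 dispersion, and 200 changed probes ease the adjustment more than the 3 called in the real comparison. Recovery in the real data may therefore be lower.

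The depth sets the precision. In the 8 deeper libraries a probe at the median had 76 to 224 counts, and in the low-yield library 9. Spearman correlations of the deposited values were 0.807 to 0.976 among the 8 libraries and 0.526 to 0.645 with the low-yield one. The first principal component, 50.7% of the variance of the scaled log2 values, put the low-yield library at 52.6 and the others between −19.2 and 6.07. Without it the first component took 44.8% and ran from −30.6 (1KO.1TG early R replicate 2) to 22.4 (3KO.7TG early bx replicate 1). No pair of replicates was alike within counting noise (chi-square per degree of freedom of 59.5 or more).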

Results

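Transcripts of kidney grafts from genetically modified pigs carried by rhesus macaques were counted with the nCounter Human Organ Transplant Panel, a hybridisation assay in which each probe counts single RNA molecules without amplification. The RNA came from formalin-fixed, paraffin-embedded renal biopsies. There were 9 libraries in 3 groups of 3, which the labels call 1KO.1TG early R, 3KO.7TG early bx and 3KO.7TG late R. 1KO.1TG and 3KO.7TG are the 2 donor pig lines; the labels name none of their altered genes and spell out neither R nor bx. The table held 767 probes, most of them named by human gene symbols, and each group's samples are called replicates 1 to 3 as in the labels. Total counts were 1042595, 1475345 and 21725 in 1KO.1TG early R, 824446, 657340 and 1191998 in 3KO.7TG early bx, and 803232, 1620151 and 1599943 in 3KO.7TG late R. Replicate 3 of 1KO.1TG early R, called the low-yield library from here on, thus held 51.4-fold fewer counts than the median of the other 8. Probes for viral genes gave 1 to 17 counts in every library, and 79.5% of all probes lay at or below 17 counts in the low-yield library against 15.0% to 24.0% in the other 8, so most of its values could not be told from background.

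The balance of macaque to pig reference signal varied within every group. The panel carried probes marked as macaque and as pig for 4 reference genes (GUSB, SDHA, UBB and STK11IP). How specific each is to its species was not checked. The mean log2 ratio of macaque to pig signal over the 4 genes served as a species index. It was −1.75 ± 1.05 (SD, n = 3) in 1KO.1TG early R, −2.69 ± 1.20 in 3KO.7TG early bx and −1.99 ± 0.80 in 3KO.7TG late R. Single libraries ranged from −3.62 in 3KO.7TG early bx replicate 1 to −0.56 in 1KO.1TG early R replicate 2. The groups did not differ beyond this spread (exact two-sided permutation p = 0.4, 0.5 and 0.9, adjusted p = 0.75, 0.75 and 0.9 over the 3 comparisons; 3 against 3 cannot go below 0.1). Over the 8 libraries other than the low-yield one, the mean level of 15 kidney parenchyma genes, such as UMOD (uromodulin) and AQP2 (a water channel), fell with the index (Pearson r = −0.97, exact permutation p = 2.23e-04, adjusted p = 0.0013; Spearman rho = −0.93, exact permutation p = 0.0022). The mean level of 23 monocyte and macrophage genes rose with it (r = 0.89, exact permutation p = 0.0033, adjusted p = 0.010). By rank this rise did not pass (rho = 0.81, exact permutation p = 0.022, adjusted p = 0.065). Adjustment was over 6 such relations. Without the 2 libraries farthest from the median index, r was −0.94 and 0.78. With each group's mean removed, r was −0.97 and 0.88. With the low-yield library included, r was −0.80 and 0.74. The index itself ran with library size (r = 0.83 with the log2 effective size), and 7 of the 15 kidney probes gave at most 34 counts in each of the 8 libraries. These 7 had r = −0.94, and 8 other-organ probes as low had r = −0.87, so background counts over larger libraries can give part of such values. With size removed these 2 sets had r = −0.80 and −0.57. The whole other-organ list of 10 probes had r = −0.94, and −0.80 with size removed. For the whole kidney list these were −0.97 and −0.89, so the fall was not particular to kidney genes. The 4 kidney probes over 34 counts throughout had r = −0.98, and −0.93 with size removed, but they were not uniform. UMOD had r = −0.93, GATA3 −0.97, VEGFA −0.27 and APOE 0.71. With size removed the monocyte and macrophage list had r = 0.65.

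**Figure D1:**
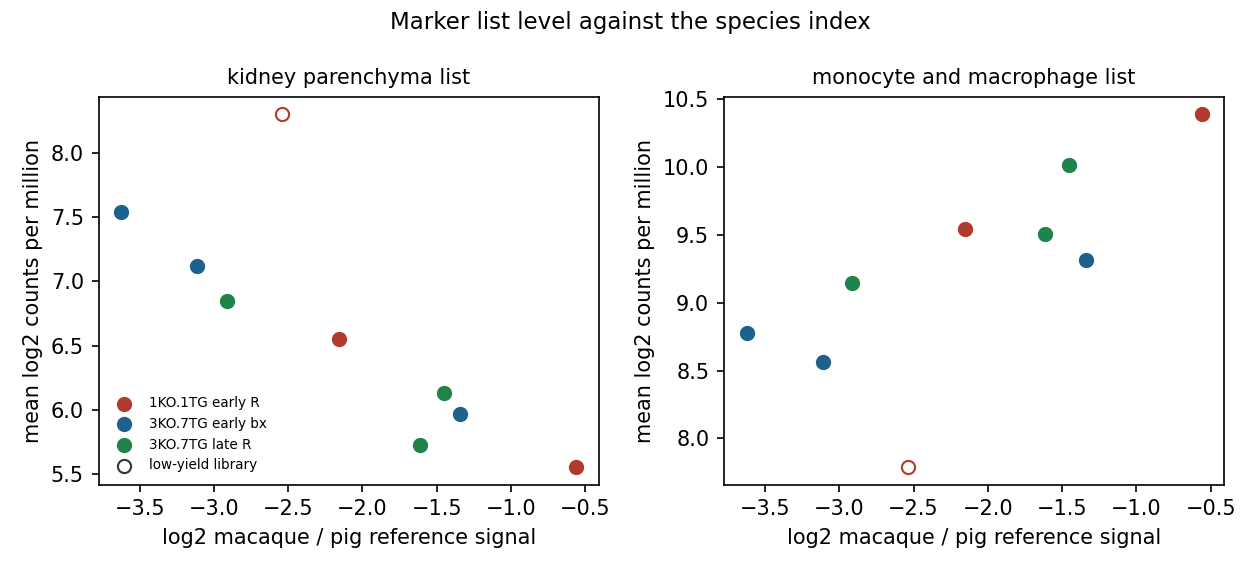
Mean log2 CPM of the kidney parenchyma list (left) and of the monocyte and macrophage list (right) against the species index, the mean log2 ratio of macaque to pig reference signal, for each of the 9 libraries, coloured by group. Over the 8 filled points r was −0.97 and 0.89; the open point is the low-yield library, which was left out of those values.

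The first comparison asked how grafts of the 2 donor lines differed among the samples labelled early (1KO.1TG early R against 3KO.7TG early bx). The 2 groups also differ in the label R against bx, which cannot be told apart from donor line here. This comparison was dominated by transcripts of a list written beforehand of human transgenes expected in the 3KO.7TG line from field knowledge. CD46, a membrane regulator of complement, was 202.7-fold lower in 1KO.1TG early R (log2 fold change −7.66 ± 0.54 SE, limma adjusted p = 4.14e-06). THBD, the endothelial anticoagulant receptor thrombomodulin, was 152.8-fold lower (−7.26 ± 0.78, limma adjusted p = 2.41e-04), and CD47, a signal that restrains phagocytosis, was 42.5-fold lower (−5.41 ± 0.61, limma adjusted p = 2.82e-04). All 3 libraries of one group lay below all 3 of the other for each of these genes. CD46 gave 102, 170 and 11 counts in 1KO.1TG early R and 14032 to 30759 in 3KO.7TG early bx. Together the 3 probes took 4.05% to 9.95% of all counts in 3KO.7TG early bx and 0.0876% to 0.193% in 1KO.1TG early R. Their counts in the low-yield library (11, 19 and 12 for CD46, THBD and CD47) were at or near background. Without it the folds were 200.7, 159.4 and 30.1, and all 3 genes still passed. The THBD fold depended most on single libraries, being 64.8 without replicate 1 of 1KO.1TG early R and 303.7 without replicate 2 (limma adjusted p = 3.42e-04 and 4.05e-06).

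Of the 2 other measured genes of the transgene list, TNFAIP3, an inhibitor of NF-κB signalling, had a log2 fold change of −1.95 ± 0.67 and did not pass (limma adjusted p = 0.245), although its groups did not overlap. CD55, a second regulator of complement, had a log2 fold change of 1.07 ± 0.60 (limma adjusted p = 0.486), with 211, 817 and 11 counts in 1KO.1TG early R and 126, 69 and 226 in 3KO.7TG early bx. The list as a whole was called lower (fry adjusted p = 0.0021; adjusted p = 0.22 with an estimated correlation). Adjusted over the list alone, 4 of its 5 genes passed, TNFAIP3 being the addition. Without the low-yield library 3 passed, and TNFAIP3 was no longer among them.

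No gene was called higher in 1KO.1TG early R with limma over all 9 libraries, while 101 of 767 probes had an unadjusted p under 0.05, 49 of them higher and 52 lower (38.4 in all by chance). Without the low-yield library there were 154, 100 of them higher and 54 lower, and without replicates 1 and 2 of 3KO.7TG early bx there were 57 and 62. Groups did not overlap for 106 probes, 13.8% against the 10% that chance gives. The 5 smallest p-values on the higher side belonged to CEACAM3, PPBP, FCGR2B, SOCS3 and CSF3R, with log2 fold changes of 2.34 ± 0.59, 3.09 ± 0.79, 2.29 ± 0.59, 2.76 ± 0.72 and 2.24 ± 0.60 (limma adjusted p = 0.170 for each). CEACAM3 and CSF3R, the receptor for granulocyte colony-stimulating factor, are granulocyte genes, and PPBP is a platelet chemokine. The neutrophil list was not called (median log2 fold change 1.503, 0.81 on the unscaled values, 10 of 11 members above 0, fry adjusted p = 0.194). Adjusted over the list alone, 3 of its members passed, and without replicate 1 of 1KO.1TG early R the list was called higher (median 2.54, fry adjusted p = 0.048). That fit left replicate 2 and the low-yield library in the group. The low-yield library had a list mean of 7.18 log2 CPM, against 5.34 to 5.76 in 3KO.7TG early bx. Background counts over its small size can raise such values, since 79.5% of its probes lay at or below 17 counts. Camera gave the neutrophil list adjusted p = 4.12e-05 with a preset and 0.33 with an estimated correlation. The monocyte and macrophage list had 12 of 23 members above 0, with a median of 0.01 that was −0.25 after median centring (fry adjusted p = 0.682). Without the low-yield library 22 of its 23 members lay above 0 with a median of 1.06, still short of a call (unadjusted fry p of 0.049 in limma, fry adjusted p = 0.255), and without replicate 2 the median was −0.38. The coagulation and platelet list had 8 of 10 members above 0 (median 0.72, −0.02 on the unscaled values, fry adjusted p = 0.697), with a median of 1.80 without the low-yield library and 0.27 without replicate 2 (fry adjusted p = 0.352 and 0.333). The species index beside these lists was 0.94 higher in 1KO.1TG early R, and 1.33 higher without the low-yield library. Neither went beyond its spread (exact permutation p = 0.4 and 0.3).

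The count on the higher side depended on single libraries. Without the low-yield library, limma called 10 genes higher and 4 lower; those groups of 2 and 3 were fitted with the spread pooled over all groups. The calls were chosen for naming after their values were seen. The granulocyte and monocyte products S100A9 and S100A8 were 65.2-fold and 51.3-fold higher (log2 fold changes 6.03 ± 1.11 and 5.68 ± 1.08, limma adjusted p = 0.032 for both), MMP9, a neutrophil gelatinase, was 20.3-fold higher (4.34 ± 0.81, limma adjusted p = 0.032), and the platelet chemokines PPBP and PF4 were 16.9-fold and 9.29-fold higher (limma adjusted p = 0.0010 and 0.047). FCGR2B, LILRB2, BTG2, CDKN1A and KRT8 were the other genes called higher, by log2 values of 2.12 to 2.82, and SOCS1, an inhibitor of cytokine signalling, joined the 3 transgene-list genes on the lower side (−1.72 ± 0.36, limma adjusted p = 0.047). Without replicate 1 the call was also 10 higher and 4 lower, but none of the 10 higher genes was shared: they included CCL20, with 768 counts in replicate 2 and 3 to 11 in every other library, and IL1R2, PTGS2, PADI4 and TREM1, and complement C3 was called lower. Without replicate 2 only CD46, CD47 and THBD were called.

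**Figure D2:**
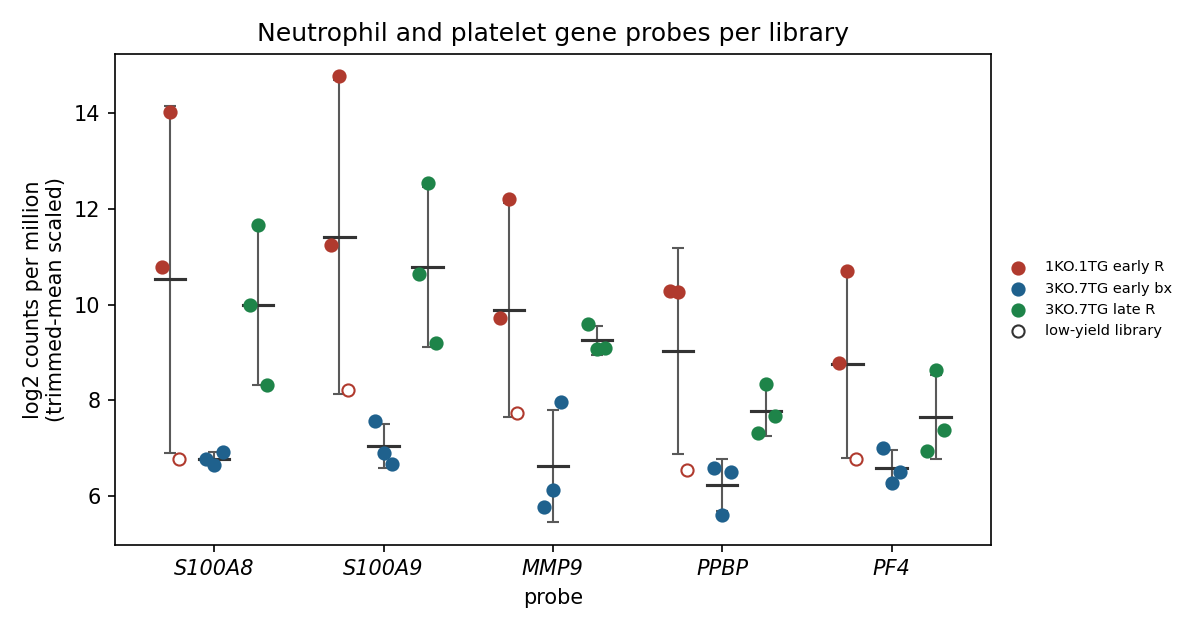
Log2 CPM (counts scaled to library size) of the neutrophil genes S100A8, S100A9 and MMP9 and the platelet chemokine genes PPBP and PF4 in each library, with group means (bars) and SDs (error bars, n = 3). Replicates 1 and 2 of 1KO.1TG early R lie above all 3 3KO.7TG early bx libraries for every one of the 5 genes, whereas the low-yield library (open points) does not for S100A8, MMP9, PPBP and PF4.

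MHC class I was the only other list called between the early samples, and the call was fragile. It was lower in 1KO.1TG early R (fry adjusted p = 0.040; adjusted p = 0.33 with an estimated correlation), with all 9 members below 0 and a median log2 fold change of −0.49. None of its members passed singly. HLA-F was at −0.87 ± 0.38, B2M (the shared light chain) at −1.87 ± 0.89 and HLA-G at −2.11 ± 1.95 (limma adjusted p = 0.3495, 0.399 and 0.742), the last turning to 0.61 without replicate 2 of 1KO.1TG early R. The call held in 8 of 29 alternative settings. It ended without the low-yield library (median −0.43, fry adjusted p = 0.255) or replicate 2 of 1KO.1TG early R (0.070), without any 1 of the 3 3KO.7TG early bx libraries (0.074, 0.178 and 0.212 for replicates 1 to 3), and without replicate 1 or 3 of 3KO.7TG late R (0.134 and 0.137). It also ended when the transgene list was left out of the lists adjusted over (0.076), and the median turned to 0.12 when libraries were scaled on the pig reference probes. Type I interferon-induced genes had 15 of 17 members below 0 (median −1.26, fry adjusted p = 0.119) and were called in 5 of 29 alternative settings, among left-out libraries without replicate 2 of 3KO.7TG late R (fry adjusted p = 0.028), while camera gave adjusted p = 5.86e-05 with a preset and 0.33 with an estimated correlation. MX2 was at −2.06 ± 0.54 and XAF1 at −1.92 ± 0.58 (limma adjusted p = 0.170 and 0.206); 8 members passed when adjusted over the list alone, and none without the low-yield library. The complement list was not called (median −0.49, turning to 0.25 on the pig reference probes, fry adjusted p = 0.055). It was called in 4 of 29 alternative settings, among left-out libraries without replicate 2 of 3KO.7TG late R (fry adjusted p = 0.028), and camera gave adjusted p = 0.039 with a preset and 0.33 with an estimated correlation. Its fry p rested on CD46, without which the adjusted p was 0.515, and C3 was at −2.08 ± 0.68 (limma adjusted p = 0.245). The kidney parenchyma list (median −0.32, turning to 0.12 without replicate 2 of 1KO.1TG early R and to 0.88 on the pig reference probes), with UMOD at −2.36 ± 0.95 and AQP2 at −3.02 ± 1.28 (limma adjusted p = 0.318 and 0.3495), and the 13 remaining lists were not called (fry adjusted p of 0.682 to 0.697). Among them, MHC class II genes had 10 of 11 members below 0 (median −0.91), but 6 of 11 above 0 without the low-yield library (median 0.04), and the median of interferon-γ-induced genes went from −0.44 to −0.06. The 13 cover interferon-γ-induced, MHC class II, T cell, NK and cytotoxic, B cell and plasma cell, dendritic and mast cell, endothelial, inflammatory cytokine, fibrosis, tubular injury, checkpoint, other-organ and housekeeping genes.

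The second comparison set the 2 donor lines against each other among the samples labelled R (1KO.1TG early R against 3KO.7TG late R), and CD46, CD47 and THBD were again the genes called. Donor line cannot be told apart from early against late in it. CD46 was 185.5-fold lower in 1KO.1TG early R (log2 fold change −7.54 ± 0.54, limma adjusted p = 5.00e-06), THBD was 107.4-fold lower (−6.75 ± 0.78, limma adjusted p = 3.53e-04) and CD47 was 42.2-fold lower (−5.40 ± 0.61, limma adjusted p = 3.53e-04), with no overlap between the groups. The THBD fold was 45.6 without replicate 1 of 1KO.1TG early R and 213.2 without replicate 2. TNFAIP3 stood at −2.13 ± 0.67 (limma adjusted p = 0.645) and CD55 at 0.26 ± 0.62 (limma adjusted p = 0.940; −0.51 without replicate 2 of 1KO.1TG early R). The transgene list was called lower (fry adjusted p = 0.0016; adjusted p = 0.061 with an estimated correlation). No gene was called higher with limma, and 51 probes had an unadjusted p under 0.05 (78 without replicate 1 of 1KO.1TG early R, 31 and 33 without replicates 2 and 3 of 3KO.7TG late R). The smallest p-values on the higher side were those of CSF3R (1.98 ± 0.53), CEACAM3 (1.69 ± 0.50), PRF1, the pore-forming protein of cytotoxic cells (1.28 ± 0.40), MPIG6B (2.27 ± 0.73) and MT1A (2.22 ± 0.72), with limma adjusted p of 0.515 to 0.645. Without the low-yield library PPBP was called as well, 5.68-fold higher (log2 fold change 2.51 ± 0.43, limma adjusted p = 0.033). Without replicate 1 of 1KO.1TG early R 6 genes were called higher and 4 lower.

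Other lists were not called between the samples labelled R. MHC class I was the nearest (median −0.58, fry adjusted p = 0.072; −0.35 and 0.459 without the low-yield library), with HLA-F at −1.01 ± 0.39 (limma adjusted p = 0.727). It was called without replicate 1 or 2 of 1KO.1TG early R (fry adjusted p = 0.0037 and 0.039). The complement list (median −0.43, 0.07 on the pig reference probes, −0.09 without the low-yield library, fry adjusted p = 0.117) owed its small p to CD46, without which the adjusted p was 0.776. The neutrophil list had 9 of 11 members above 0 (median 1.30, −0.10 on the unscaled values, fry adjusted p = 0.461), and without replicate 2 of 1KO.1TG early R its median was 0.40. MHC class II and type I interferon-induced genes had medians of −1.04 and −0.53 (fry adjusted p = 0.461 for both), and that of MHC class II shrank to −0.33 without the low-yield library. All remaining lists had fry adjusted p of 0.727 or more; the coagulation and platelet list, which holds THBD, was called lower only without replicate 2 of 1KO.1TG early R (fry adjusted p = 0.039), where its median turned from 0.54 to −0.29. Over all libraries and without THBD the list pointed higher (fry adjusted p = 0.776). The species index was 0.24 higher in 1KO.1TG early R, and 0.63 higher without the low-yield library.

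The third comparison asked how 3KO.7TG grafts labelled late R differed from those labelled early bx, and no gene or list was called. Late against early cannot be told apart from R against bx in it. With limma, 13 of 767 probes had an unadjusted p under 0.05 (38.4 by chance), 11 of them higher in late R. Single libraries moved that count: it was 6 to 41 without each of the early bx libraries (8, 6 and 41 for replicates 1 to 3), and 25 and 27 without replicates 2 and 3 of 1KO.1TG early R. It was 44 with the 2 groups alone and 128 with library weights, with no gene called in any of these fits. The smallest limma adjusted p was 0.990 in the main fit and 0.911 without the low-yield library. Among the named genes, the lowest limma adjusted p in any alternative fit was 0.084, for BTG2 and MMP9. CD46, CD47 and THBD were at similar levels, with log2 fold changes of −0.13 ± 0.59, −0.01 ± 0.64 and −0.51 ± 0.85, as was TNFAIP3 (0.18 ± 0.70). CD55 was at 0.81 ± 0.56 without passing (limma adjusted p = 0.990), its 3 late R libraries all lying above the 3 of early bx. The smallest p-values on the higher side were those of S100A9 (3.74 ± 1.27), MMP9 (2.52 ± 0.90), BTG2 (1.46 ± 0.53), the monocyte chemoattractant CCL2 (1.67 ± 0.67) and VWF, the von Willebrand factor of endothelium and platelets (1.58 ± 0.66). For each of these 5 genes all 3 late R libraries lay above all 3 early bx libraries, but 3 against 3 libraries overlapped nowhere for 78 probes in all, 10.2% against the 10% that chance gives. Genes with small p-values on the lower side included ISG15 (−1.38 ± 0.56), SOCS1 (−0.97 ± 0.42), RORA (−1.20 ± 0.56) and PTPRO (−1.01 ± 0.49).

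All 21 lists had a fry adjusted p of 0.938 in this comparison. The monocyte and macrophage list had 22 of 23 members above 0 (median 0.64), with SLC11A1 at 1.28 ± 0.70 and TREM1 at 1.30 ± 0.74. The coagulation and platelet list had 7 of 10 above 0 (median 0.81) and the tubular injury list 14 of 19 (median 0.63). Kidney parenchyma genes had 14 of 15 members below 0 (median −0.61), UMOD at −1.74 ± 1.01, and type I interferon-induced genes 14 of 17 (median −0.46, turning to 0.09 on the unscaled values). The other-organ list had all 10 members below 0 (median −0.67), as low as that of the kidney list, although 8 of its probes gave at most 24 counts in any library and so lay near background. Camera with a preset correlation called these 6 lists, and with an estimated correlation it called none (adjusted p of 0.80 to 0.90). The species index was 0.70 higher in late R, within its spread.

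Both comparisons against 3KO.7TG early bx use the same 3 libraries, so chance alone makes their fold changes alike. Because the late R comparison called no gene, none could be called in both, and the 0 that independent lists would share carries no information. The log2 fold changes of the 2 comparisons correlated across probes, which are not independent replicates, with r = 0.53, against a mean of 0.52 and a highest value of 0.60 in 100 simulations of unchanged groups measured against the same libraries. The covariance was 0.36 against a simulated 0.30, a difference of 0.06, and the same sign was seen for 67.4% of probes against a simulated 66.7%. The 3 shared libraries could not be split into 2 sets of at least 2.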

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

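Scaling on species probes, no scaling, library weights, the subtraction of viral probe counts and the fits with 2 changes were chosen after the data were seen. CD46 and THBD were called lower in 1KO.1TG early R in both donor-line comparisons under all 27 alternative fits, with log2 fold changes of −8.44 to −6.78 and −8.25 to −6.02 against 3KO.7TG early bx; CD47 was called in 26, all but the unscaled values (limma adjusted p = 0.344 against early bx). No gene was called in late R against early bx in any fit, nor in both comparisons against early bx. For 1KO.1TG early R against early bx, main counts were 3 genes and 2 lists. Gene counts were 33 with a quality weight per library (23 higher, 10 lower), 8 scaled on macaque probes (1 higher, 7 lower), and, without the low-yield library, 5 on macaque probes and 26 with a replicate block. List counts were 4 with median centring and on macaque probes; 1 with quantile normalization, pseudocount 10, the 2 groups alone, no voom weights, library weights, pig probes or viral mean subtracted; 5 with camera at a preset correlation; 0 with camera at an estimated correlation, as deposited, and, without the low-yield library, on pig probes or with a replicate block. Against late R, the count of lists, 1, became 2 with the filter on low means, 6 with preset camera, and 0 with estimated camera, as deposited, and without the low-yield library on pig probes. In late R against early bx, preset camera called 6 lists (3 higher, 3 lower). Leaving out each library in turn gave 3 to 14 genes and 1 to 4 lists for the first comparison, 3 to 10 genes and 1 to 3 lists for 1KO.1TG early R against late R, and 0 genes and 0 lists for the third. The MHC class I median against early bx reversed to 0.12 on pig probes, and to 0.32 with the low-yield library also left out. The causes were not tested. Scalings shifted the median of all probes in the first comparison from −0.07 to −0.32 (median), 0.15 (housekeeping), 0.82 (pig), −0.43 (macaque) and −0.77 (none).

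With a replicate block the gene counts stayed at 3, 0 and 3 and the list counts became 1, 0 and 2. Deviations of equally numbered libraries correlated at −0.45 to 0.48, over 0.1 in 3 of 9 pairs, and no library was closest to its own number in both other groups. That search spans the 2 donor lines, so it cannot decide whether the 3KO.7TG early bx and late R libraries are paired. Between those 2 groups the values were 0.28, −0.34 and 0.48 for numbers 1 to 3, which leaves a pairing open. The labels state none, so none was used in the main fit. Of 3586 named-gene values under alternatives, 36 newly passed, 2 no longer passed and no called one reversed; 57 uncalled ones changed sign. DESeq2 was not run, by choice, as the deposited unit is log2, although the recovered counts would have allowed a count model. Depth limits the low-yield library most, with 79.5% of its probes at or below the highest viral probe count.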

Other observations

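The tests of scaling and of the low-yield library as reasons for the transgene-list difference were chosen after the result was seen, as were the tests of background counts in the kidney list, the check on library totals and the stricter reading of 2 bounds below; the others were fixed before it. Beyond the comparisons, replicate 2 of 1KO.1TG early R gave the highest counts of several granulocyte and inflammatory genes, which were picked because it was highest in them. It gave 31242 counts of S100A9, 18580 of S100A8, 2311 of LCN2, 1220 of TREM1, 768 of CCL20, 705 of PTGS2 and 436 of IL1R2. In the other 8 libraries the highest counts of these genes were 8948, 4929, 220, 165, 11, 96 and 52. Other inflammatory genes did not follow: TNF gave 124 counts in it and 614 in replicate 3 of 3KO.7TG late R, and IL6 gave 47 in it and 100 in replicate 2 of that group. Its UMOD count was 815, against 5185 to 31665 in the other 7 deep libraries, and its species index, −0.56, was the highest of the 9.

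The species index raised the hypothesis that the balance of macaque and pig RNA sets marker levels across biopsies of every group, and the lists did not all follow it. Over the 8 deep libraries, kidney parenchyma (r = −0.97) and monocyte and macrophage genes (r = 0.89) passed adjustment over 6 relations (exact permutation, adjusted p = 0.0013 and 0.010). By Spearman rank only the kidney list passed (exact permutation, adjusted p = 0.013, against 0.065). The 2 lists kept r of −0.94 and 0.78 without the 2 extreme libraries. B cell and plasma cell genes (r = 0.67, adjusted p = 0.15) and neutrophil genes (r = 0.55, adjusted p = 0.23) stayed open, with r of 0.24 and −0.10 without those 2 libraries. T cell genes also stayed open (r = 0.28, adjusted p = 0.50). Their r was below the bound of 0.3 set beforehand by less than its spread, and it was 0.34 without those 2 libraries and 0.66 with group means removed. NK and cytotoxic genes lacked the rise predicted (r = −0.48, adjusted p = 0.29; −0.58 without the 2 libraries and −0.61 with group means removed). Background counts over libraries of unequal size are a technical reason for part of the kidney relation, since the index ran with library size (r = 0.83). For the 7 kidney probes at or below 34 counts (r = −0.94) this reason has what it needs, because 8 other-organ probes as low had r = −0.87. With size removed r was −0.80 and −0.57, so library size may account for only part of it. The whole other-organ list of 10 probes had r = −0.94, and −0.80 with size removed, so the fall was not particular to the kidney list. The mean of the 4 kidney probes over 34 counts had r = −0.98, and −0.93 with size removed. Only 2 of these 4 fell with the index by themselves, UMOD (r = −0.93, −0.87 with size removed) and GATA3 (−0.97 and −0.92). Background as the reason is argued against for these 2. VEGFA (−0.27 and 0.42) and APOE (0.71 and 0.44) did not fall once size was removed, so this does not extend to the 4 as a set. That macaque myeloid RNA displaces pig parenchymal RNA may hold for such genes as UMOD (r = −0.93), as a hypothesis. Library size remains tied to the index, and sampling of different kidney regions, which was not tested, could produce the same values.

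CD46, CD47 and THBD were far lower in 1KO.1TG early R than in 3KO.7TG early bx. Scaling as the reason is argued against, since the smallest of the 3 changes over 7 scalings was 4.79 ± 0.82 in size on the log2 scale. The low-yield library is argued against as well, with a smallest size of 4.91 ± 0.46 without it. Macaque transcripts read by the human probes would follow the macaque signal if their level per macaque RNA were steady. Relative to the macaque reference probes the smallest size was 5.65 ± 0.57. That scaling moved the median of all probes only from −0.07 to −0.43, so it speaks against a change in macaque share alone. Macaque transcripts of these 3 genes changing by themselves were not tested. A hypothesis that stays open is that the 3KO.7TG line carries these 3 genes as transgenes and the 1KO.1TG line does not; the labels name no transgene, and a difference in how probes bind each line's own transcripts was not tested. By the same reading the CD55 probe gave no sign of a transgene in one line alone.

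The 10 genes called higher in 1KO.1TG early R without the low-yield library include neutrophil and platelet genes. A larger share of macaque RNA of every kind stays open as a reason. Relative to the macaque reference probes their median log2 fold change was 2.45 (lower quartile 1.89, median SE 0.58), against 3.02 (median SE 0.56) before. That met the bound set beforehand, but the genes had been picked for large changes and the scaling moved them by a median of only 0.56, so the bound was too easily met, and only 1 of the 10 was still called. Why the other calls ended was not tested. That the low-yield library is too shallow to show them remains open too. All 10 genes had an expected count over 34 there from the scaled levels of the other 2 replicates, and all 10 lay below 0.5 of it. The bound set beforehand would thus have ruled this reason out. A check from library totals, added after that value was seen, held for only 5 of the 10, since the trimmed-mean factor of 2.71 of that library raises the expectation, and it was therefore left open. S100A9 had 17 counts there, where 890.2 were expected from scaled levels and 256.2 from totals. A real difference between the animals or biopsies of this group, and poor RNA in the low-yield one, cannot be told apart.

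Other splits of the 6 samples into 3 and 3 were refitted for each comparison, and 10 splits are too few for a share under 0.05. For 1KO.1TG early R against 3KO.7TG early bx the real split called 3 genes and the highest other 0, so 1 split of 10 reached the real count. The same numbers, 1 of 10 with 3 against 0, held against 3KO.7TG late R. For 3KO.7TG late R against early bx the real split and all others called 0, so 10 of 10 reached it.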
